A study of Rattus norvegicus with 2 samples.

How the data were processed

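The data were 2 Affymetrix GeneChip arrays of total RNA from the adductor muscle of male Lewis rats, an inbred strain. One array was hybridised with muscle from the limb pricked with a fine needle and 1 with muscle from the untreated limb. Per the labels' protocols, RNA was purified on silica columns (RNeasy) and labelled with biotin in a single amplification cycle, which copies transcripts from their 3' ends. The labels do not give the number of animals, so it is open whether each sample came from 1 rat or from several.

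The deposited table held 1 value per probe set and array, a linear signal intensity made by the authors with MAS5, per the submitters' processing notes. MAS5 is the manufacturer's algorithm that combines perfect-match and mismatch probes into 1 signal per probe set and then multiplies each array by a single factor. The software version and the scaling target are not given in the sources used here, and detection calls were not used here. The mean signal after trimming 2% of probe sets at each end was 76.5 on both deposited columns, as scaling to 1 common target would give. Each column held 31099 probe sets, of which 57 were manufacturer's controls and 31042 were used. A MAS5 signal has no replicate error of its own, and low signals carry the largest relative noise. The number of arrays, 1 per group, limits the precision of every value.

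Probe sets were named through the platform annotation, which listed 21268 probe sets. Of these, 20832 had 1 gene symbol and 436 had several. A further 9780 probe sets had no gene listed and are unnamed here. Of the probe sets with 1 symbol, 20764 were matched by gene identifier to the current rat RefSeq gene table (assembly GRCr8), which was used for names and synonyms alone and changed 0 symbols. No genomic coordinates are given, because no genome build is named for the array. Probe sets with several genes were left out of the gene counts.

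The following choices were made before the data were examined. Signals were used with the authors' scaling. A floor was set at the median of all non-control signals on both arrays, which came to 19.8, and lower signals were raised to it before the log2 ratio of stimulated over control was taken. A probe set was called measured where at least 1 array reached the floor, which held for 16644 probe sets. Where 1 array lay below the floor, the fold is a lower bound and is written as "at least". Each gene was represented by its measured probe set with the highest mean log2 signal, which gave 9956 genes, of which 8995 reached the floor on both arrays. Genes were counted as higher or lower at a 2-fold difference, with no test and no p-value, since each group has 1 array. Named genes were the 10 with the largest ratio in each direction among plainly named genes measured on both arrays, the 5 brightest in each direction with the other array below the floor, up to 4 members of each gene list with the largest absolute ratio, and Pax7, Myod1, Myog, Mstn, Vegfa and Hgf wherever measured. This rule named 133 genes, and those that carry each comparison are given in the text. Names without a characterised gene were skipped in the parts chosen by size. Other list members named below, and Apoe and Fabp5, were chosen after their values were seen.

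A total of 29 gene lists (pathways, fibre types and markers of other cell types) were fixed in advance. For each list the median log2 ratio of its measured members was set against the medians of 10000 random lists of the same size, drawn from 20 bins of mean log2 signal. A list is described as standing apart where its median lay above 97.5% or below 2.5% of the random medians. That percentile describes these 2 arrays and is not a test of the treatment, and genes of a list are not independent of each other. With random genes, 1.45 of 29 lists would stand apart.

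The only repeat measurement within the pair of arrays was that of different probe sets of the same gene. Over 2174 genes with at least 2 probe sets above the floor on both arrays, the log2 ratios of the 2 brightest differed with an SD of 0.44 (95% bootstrap interval 0.43 to 0.46), which is 0.31 for a single probe set. For a single probe set it was 0.35 in the 725 dimmest of these genes and 0.27 in the 725 brightest. This spread holds probe-level error and transcript isoforms, and leaves out the variation between limbs and between animals. Across the 2174 genes, the 2 log2 ratios correlated with a Pearson r of only 0.34, and of 0.25 in the 725 dimmest.

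The counting was tested on simulated data made from the signals of the same arrays, with the spread of a single probe set and 200 genes altered. Of 50 genes made 4-fold higher, 100% were counted, and of 50 made 4-fold lower, 82% were. For differences of 2.83-fold, 96% of the higher and 78% of the lower genes were counted. Of 9492 unaltered genes, 7 were counted in either direction. The simulation gave bright and dim genes the same spread and held no variation between limbs or animals. It therefore gives no rate of false calls for the real arrays. Of 200 lists of unaltered genes, 5% fell outside the central 95% of random lists. Those lists were themselves drawn at random from genes with independent noise, so about this share was fixed by the design. It does not show how often a list of genes that vary together would stand apart.

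Alternatives fixed in advance were 3 other scalings of the arrays (median, quantile and loess), other floors, a pseudocount equal to the floor in its place, the median over probe sets of a gene, leaving out suffixed probe sets, thresholds of 1.5-fold and 3-fold, only genes measured on both arrays, and counting probe sets. Suffixed probe sets are those whose names end in _x_at, _s_at or _a_at. The first 2 endings mark possible cross-hybridisation with other genes, and _a_at marks transcripts of the same gene. A scaling to the hybridisation spike-ins was added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.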

Results

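Gene expression was measured in rat adductor muscle, a muscle of the inner thigh, 24 hours after fine needle stimulation of the left hindlimb. The stimulus was 100 pricks with a 0.14 mm steel needle within a square of 10 mm by 10 mm. Muscle of the right limb, which was not pricked, served as the control. Each limb was represented by 1 array, so no difference below has a replicate check, none was tested, and "higher" and "lower" describe these 2 samples. The labels do not say how many rats were used or whether both pieces came from the same animal. The only error at hand is the SD of 0.31 of a single probe set's log2 ratio, from probe sets of the same gene.

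The stimulated sample had 48.9% of its probe sets at or above the signal floor of 19.8 and the control sample 51.1%. The 3'-to-5' signal ratio of the beta-actin control, a measure of RNA integrity, was 2.43 in the stimulated and 2.26 in the control sample, and that of Gapdh was 1.12 and 1.08. Across probe sets above the floor on both arrays, log2 signals correlated with a Pearson r of 0.97 across genes, which are not independent replicates. The log2 ratio of the median gene was 0.019. All 18 hybridisation spike-in probe sets, bacterial and phage sequences added in fixed amounts, were lower on the stimulated array, with a median log2 ratio of -0.38. The 24 probe sets of another set of bacterial controls (dap, lys, phe and thr), whose use is not given in the sources used here, went mostly the other way, with 18 higher, 6 lower and a median of 0.19. Scaling to the hybridisation spike-ins moved the median of all genes to 0.39, and all directions below are therefore relative to the median gene.

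The comparison asked which transcripts differed between pricked and unpricked muscle. Macrophage markers, led by Spp1 (at least 144-fold) and Gpnmb (16.9-fold), slow-fibre genes such as Tnnc1 (7.38-fold) and the load-sensing genes Csrp3 (5.81-fold) and Ankrd1 (4.07-fold) were higher in the stimulated limb. Interferon-stimulated genes such as Isg15 (6.14-fold), some cytokines such as Il6 (at least 4.77-fold) and some adipocyte markers such as Adipoq (3.38-fold) were lower. Of 14 endothelial markers, 13 lay below 0, all but 1 of them by less than 2-fold. Of 9956 measured genes, 142 were at least 2-fold higher and 142 at least 2-fold lower, which is 1.43% in each direction, and 86.5% of genes lay within 1.5-fold. At least a 4-fold difference was seen for 17 higher and 7 lower genes. The control signal was below the floor for 24 of the higher genes and the stimulated signal for 29 of the lower ones. With scaling to the spike-ins the split was 525 higher and 44 lower. Of 20 higher genes with a further measured probe set, that probe set pointed the same way for 13, and for 4 it was also at least 2-fold higher. Of 39 such lower genes, it pointed the same way for 35 and was at least 2-fold lower for 7.

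**Figure D1:**
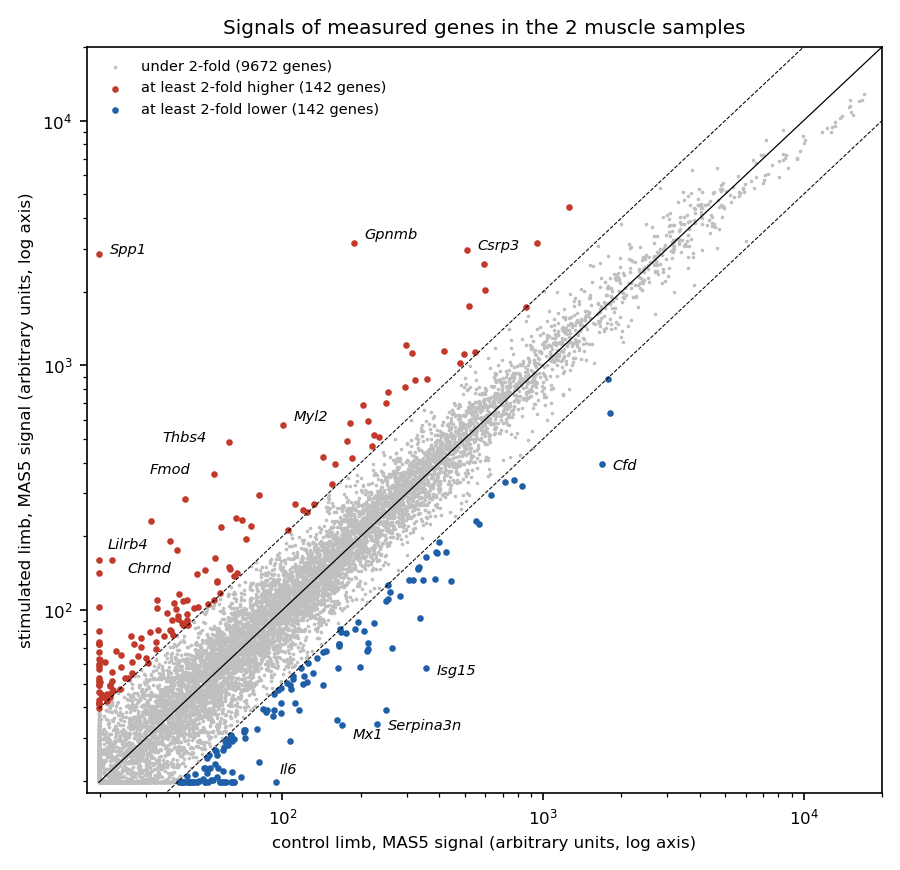
Signal of each of the 9956 measured genes in the control limb (x axis) and the stimulated limb (y axis), in arbitrary MAS5 units on log axes, with signals below the floor of 19.8 drawn at it, a solid line at equal signals and dashed lines at a 2-fold difference. Red points are the 142 genes at least 2-fold higher and blue points the 142 at least 2-fold lower, with Spp1 and Gpnmb farthest above the line.

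The largest difference in the data was that of Spp1 (Entrez gene 25353, osteopontin, a secreted phosphoprotein made by activated macrophages among other cells), with a signal of 2847 in the stimulated limb and 12.7, below the floor, in the control, at least 144-fold higher. Gpnmb, a transmembrane glycoprotein of phagocytes, was 16.9-fold higher (3165 against 188). Monocyte and macrophage markers as a list had a median log2 ratio of 0.66, above all 10000 random lists, and 22 of its 24 measured members lay above 0. In all, 8 members were at least 2-fold higher and 0 were at least 2-fold lower. Besides Spp1 and Gpnmb these included Lgals3 (galectin-3, 3.39-fold), Tyrobp (the signalling adaptor DAP12, 3.22-fold), Cd53 (2.49-fold), Ptprc (the pan-leukocyte antigen CD45, 2.33-fold) and Cd68 (2.12-fold). Cd14 (1.06-fold) and the scavenger receptor Cd163 (1.06-fold) differed by less than the probe set SD. The 2 members below 0 were the Fc receptor Fcgr3a, at least 1.48-fold lower with a control signal of 29.2, and Ccr2, a chemokine receptor of blood monocytes, at least 1.21-fold lower with one of 23.9. The brightest genes in the stimulated limb with a control signal below the floor also included receptors of myeloid cells. Lilrb4 was at least 8.11-fold and Clec7a (dectin-1) at least 5.20-fold higher, and the apolipoprotein Apoc1 was at least 7.15-fold higher. MHC class II genes, which present antigen, had a median log2 ratio of 0.45, above 9987 of 10000 random lists, with 7 of 8 members above 0, 0 at least 2-fold higher and 1, Ciita, at least 2-fold lower. Examples were RT1-DMa (1.67-fold) and RT1-Da (1.59-fold). The probe sets of Ciita, their transactivator, disagreed, at -1.14 and 0.054.

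Markers of the other blood cells did not stand apart, but most of them were not measured. Measured were 6 of 18 neutrophil, 4 of 18 lymphocyte, 4 of 10 mast cell and 4 of 11 red cell and platelet genes. The rest lay below the floor on both arrays or had no probe set of their own, so a difference in these cells could have been missed. Neutrophil markers had a median log2 ratio of 0.093 over 6 measured members, with S100a9 at -0.14. Lymphocyte markers had a median of -0.0076 over 4 members, although Cd8a was at least 3.76-fold higher and its second probe set had a log2 ratio of 1.14. Mast cell markers had a median of -0.077 over 4 members, which went both ways, since Tpsab1 was 2.97-fold higher and Cpa3 1.59-fold lower. Means of the lymphocyte and mast cell lists, 0.32 and 0.19, had the opposite sign to their medians. Red cell and platelet markers had a median of 0.23 over 4 members, with Hbb 1.22-fold and Pf4 1.66-fold higher.

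Cytokines and chemokines went both ways, with 10 of 15 measured members below 0 and 5 above. The list had a median log2 ratio of -0.44, below 9998 of 10000 random lists, with 4 members at least 2-fold lower and 0 at least 2-fold higher. Il6 had a signal of 94.3 in the control limb and lay below the floor in the stimulated limb, at least 4.77-fold lower. The chemokine Ccl20 was at least 3.02-fold lower, Cxcl10 2.20-fold and Ccl7 2.13-fold lower. Ccl3, Cxcl16 and Tgfb1 had log2 ratios of 0.86, 0.67 and 0.34. Tnf was below the floor on both arrays. Macrophage markers were higher in the same sample.

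Interferon-stimulated genes, which encode antiviral proteins, had a median of -0.79, below all 10000 random lists. Of 19 measured members, 9 were at least 2-fold lower and 0 were at least 2-fold higher. The ubiquitin-like modifier Isg15 was 6.14-fold lower (57.8 against 355), Mx1 4.99-fold, Mx2 3.35-fold and Rsad2 (viperin) 2.94-fold lower, and Irf1 had a log2 ratio of 0.019. Endothelial markers had a median of -0.60. Ddx60, another interferon-induced gene, was at least 3.22-fold lower. Complement and haemostasis genes had a median of -0.58, below all random lists, with 2 of 16 members at least 2-fold lower, Cfd (4.26-fold) and Serping1, the C1 inhibitor (2.58-fold). The initiator subunit genes C1qa, C1qb and C1qc were all lower, with log2 ratios of -0.53, -0.58 and -0.83. The macrophage list did not hold these genes, and they went the other way from its median in the same sample. The receptor genes C5ar1 (1.53-fold) and C3ar1 (log2 ratio 0.35) were the only 2 of the 16 above 0.

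**Figure D2:**
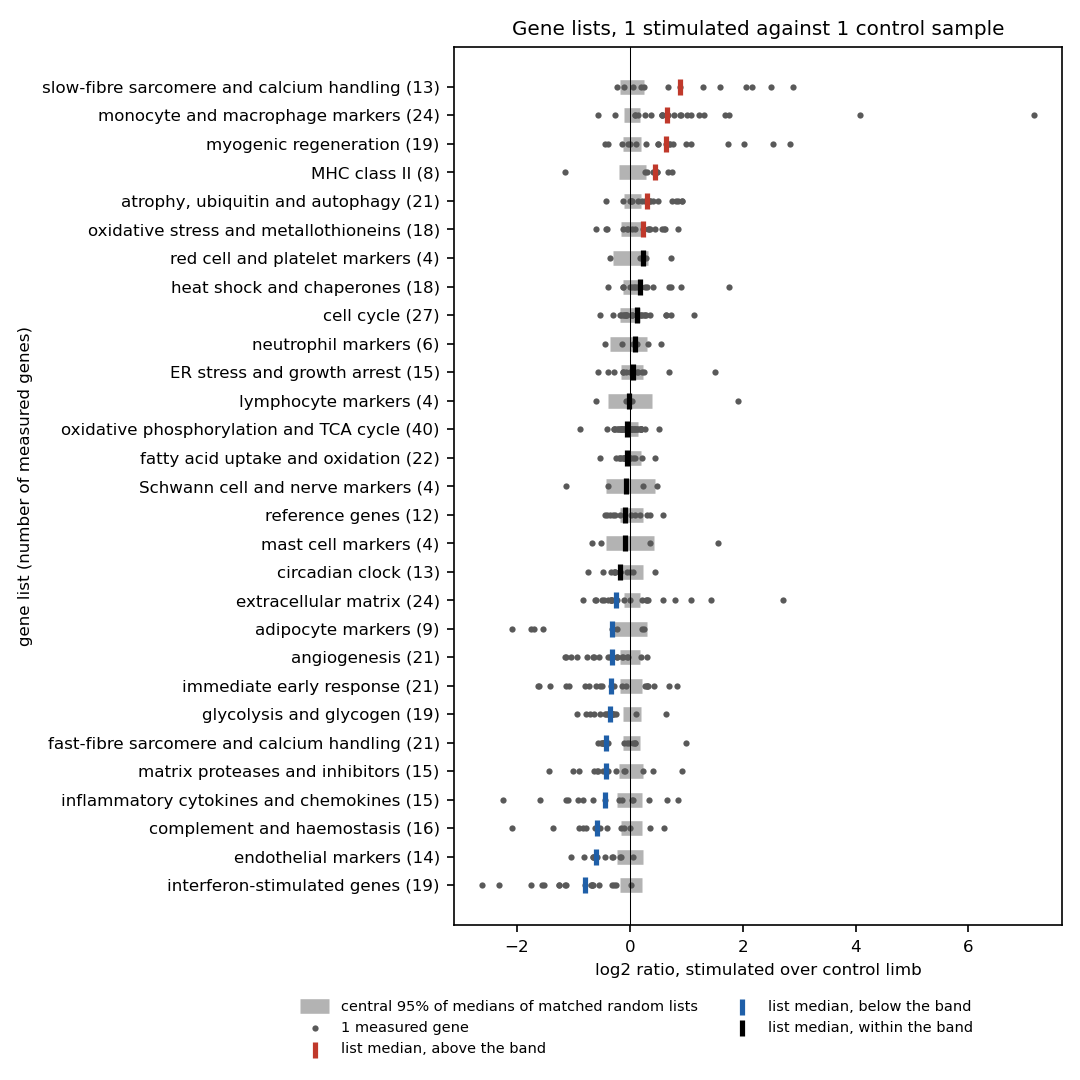
Log2 ratio of stimulated over control signal (x axis) for the measured members of 29 gene lists (y axis, number of members in brackets), with points for genes, vertical ticks for list medians, coloured where they stand apart, and grey bars for the central 95% of medians of 10000 signal-matched random lists. The slow-fibre median is 0.89 and the interferon-stimulated one -0.79.

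Slow-fibre genes had a median of 0.89, above all 10000 random lists, with 6 of 13 members at least 2-fold higher and 0 at least 2-fold lower. The median was 0.25 with the floor at the 75th percentile and 0.38 with the median over probe sets. The slow troponin genes Tnnc1 (7.38-fold, 232 against 31.4), Tnni1 (4.49-fold, with a second probe set at a log2 ratio of 2.38) and Tnnt1 (at least 4.16-fold) were higher, as were the regulatory light chain Myl2 (5.68-fold) and the slow myosin heavy chain Myh7 (at least 3.04-fold, with a second probe set at 0.19). The members did not move as 1 group, since the essential light chain Myl3 had a log2 ratio of 0.064 and myoglobin, Mb, of -0.11. Sln (sarcolipin, a regulator of the sarcoplasmic calcium pump) was 5.17-fold higher. Fast-fibre genes had a median of -0.42, below all random lists, with 0 of 21 members beyond 2-fold in either direction. Examples were Tpm1 (1.47-fold lower), parvalbumin, Pvalb (1.42-fold lower), and Myl1 (1.41-fold lower), while the fast oxidative heavy chain Myh2 had a signal of 2010 against 1008, just under 2-fold higher. With quantile normalization the median of the fast-fibre list was -0.027, within the range of random lists. The 21 genes of mean signal 5000 or more in the fast-fibre and glycolysis lists had a median of -0.42, and the 40 outside both lists one of -0.15. From a mean signal of 2000 up, these medians were -0.42 over 27 genes and 0.020 over 244. The cre spike-ins, with signals of 9747 to 15986, had log2 ratios from -0.43 to -0.29. Spike-ins of like brightness were thus lower by a like amount. This was not particular to bright ones, since all 18 spike-ins were lower, with a median of -0.38. The fast-fibre median kept its sign under spike-in scaling without reference to the median gene. Its size holds only relative to that gene. The brightest signal bin reached below a mean signal of 2000, so random lists for these genes also drew on dimmer ones.

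Thbs4 (thrombospondin 4) was 7.84-fold higher, Tnmd (tenomodulin, a tendon cell marker) 6.69-fold and the collagen-binding proteoglycan Fmod 6.58-fold higher. Of the 24 measured extracellular matrix genes, 3 were at least 2-fold higher, namely Fmod, tenascin C (Tnc, 2.71-fold) and lysyl oxidase (Lox, 2.13-fold, with a second probe set at 0.36), and 0 were at least 2-fold lower. The median of the list was nevertheless -0.24, below 9999 of 10000 random lists, and its mean was 0.094. Sparc, a collagen-binding glycoprotein, was 1.77-fold lower, and the type I collagen genes Col1a1 and Col1a2 had log2 ratios of -0.26 and -0.38. Under spike-in scaling without reference to the median gene, the median of this list was 0.14. Matrix proteases and their inhibitors had a median of -0.42, below 9999 of 10000 random lists, with Adamts4 2.69-fold and the inhibitor Timp3 1.87-fold lower and the lysosomal protease Ctsb 1.89-fold higher.

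The list fixed as myogenic regeneration, which also held genes of load sensing, had a median of 0.65, above all 10000 random lists. Of its 19 measured members, 5 were at least 2-fold higher and 0 at least 2-fold lower. Csrp3 (muscle LIM protein) was 5.81-fold higher, and the stress-responsive ankyrin repeat genes Ankrd1 and Ankrd2 were 4.07-fold and 3.35-fold higher, with a second Ankrd1 probe set at 2.13. Chrnd, the delta subunit of the acetylcholine receptor, was 7.18-fold higher, though its control signal of 22.3 was close to the floor, and Xirp1, an actin-binding protein of muscle, was 2.11-fold higher. Myog (myogenin, a differentiation factor) was 1.99-fold higher, while Myod1 (363 against 361) and the growth inhibitor Mstn (73.4 against 80.6) differed by less than the probe set SD. The growth factors Igf1 and Igf2 had log2 ratios of -0.38 and -0.44, and both other Igf1 probe sets were lower as well. The embryonic and perinatal myosin genes Myh3 and Myh8, the fetal receptor subunit gene Chrng and the growth factor Hgf were below the floor on both arrays, and Pax7 was not analysed here. The 4 genes with the largest ratios in this list act in stretch and load sensing (Csrp3, Ankrd1 and Ankrd2) and at the neuromuscular junction (Chrnd).

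Endothelial markers had a median of -0.60, below all 10000 random lists, and 13 of 14 measured members lay below 0. Of the 14, 1 was at least 2-fold lower, Selp (P-selectin, at least 2.06-fold), and 0 were at least 2-fold higher. Pecam1 was 1.74-fold lower. Plvap and Procr, both expressed by endothelium, were 3.62-fold and 3.74-fold lower, and the prostacyclin synthase gene Ptgis and the Notch-regulated Nrarp were at least 3.29-fold and 3.30-fold lower, with a second Nrarp probe set at -0.64. Angiogenesis genes had a median of -0.32, below 9997 of 10000 random lists, with 3 of 21 members at least 2-fold lower and 0 at least 2-fold higher. These were the receptors Flt1 (at least 2.22-fold, with other probe sets at -0.74 and -0.63) and Kdr (2.06-fold) and the ligand Angpt2 (2.20-fold). Tek and Tie1 are in both this list and the endothelial one, so the angiogenesis result is not independent of the endothelial one. Vegfa was 1.24-fold lower (210 against 261), with a second probe set at -0.84.

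Adipocyte markers had a median of -0.31, below 9850 of 10000 random lists, with 4 of 9 members at least 2-fold lower. That median was -0.92 with the median over probe sets and -1.54 without suffixed probe sets. The 4 were Cfd (adipsin), adiponectin (Adipoq, 3.38-fold), perilipin (Plin1, at least 3.23-fold, with a second probe set at -0.61) and Cidec (at least 2.91-fold). The other 5 lay within 2-fold, such as Fabp4 at a log2 ratio of -0.29, and 2 of them, Cidea (0.21) and Dgat2 (0.25), lay above 0. Immediate early genes had a median of -0.34, below all 10000 random lists, with 5 of 21 members at least 2-fold lower and 0 at least 2-fold higher. The lower ones were led by Egr1 (3.10-fold), Zfp36 (3.06-fold) and Fos (2.67-fold). In all, 14 members lay below 0 and 7 above, among the latter Fosl1 at 0.84 and Atf3 at 0.70. Glycolysis and glycogen genes had a median of -0.36, below all random lists, with 17 of 19 members below 0 and 0 beyond 2-fold. Pfkfb3 was 1.90-fold and the phosphorylase kinase subunit Phkg1 1.71-fold lower. Medians of the adipocyte, immediate early and glycolysis lists lay between 0.023 and 0.071 under spike-in scaling when not taken relative to the median gene. Further genes among the most different were Serpina3n, an acute-phase protease inhibitor (6.74-fold lower), the secreted phospholipase Pla2g2a (6.43-fold), the lipocalin Obp3 (4.56-fold, with a second probe set about 2-fold lower), the B-cell chemokine Cxcl13 (3.69-fold) and the retinol carrier Rbp4 (3.41-fold lower).

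**Figure D3:**
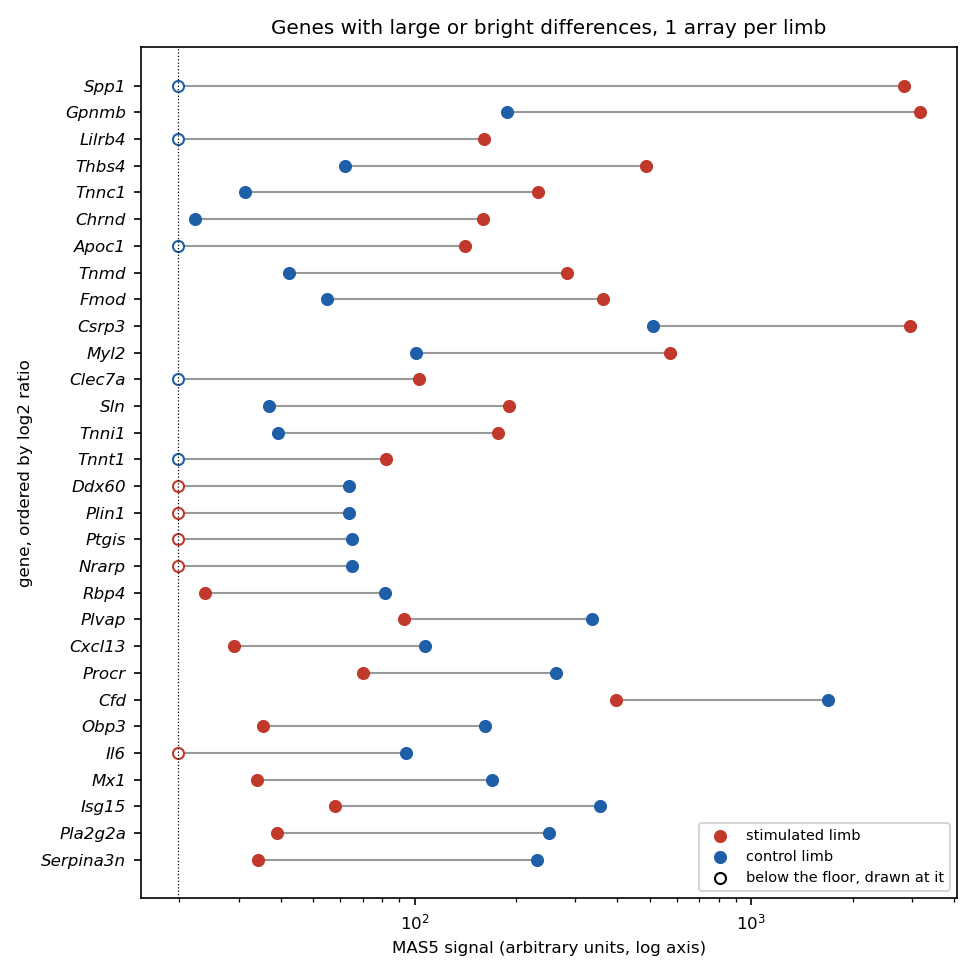
MAS5 signal (x axis, arbitrary units, log scale) of 30 genes (y axis, ordered by log2 ratio), 10 per direction with the largest ratios and 5 per direction chosen by signal with the other array below the floor, in the stimulated limb (red) and the control limb (blue), 1 array each. Open symbols are signals below the floor of 19.8 (dotted line), drawn at it, such as Spp1 in the control limb and Il6 in the stimulated limb.

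Protein breakdown genes had a median of 0.30, above 9996 of 10000 random lists, with 19 of 21 members above 0 and 0 beyond 2-fold. The lysosomal proteases Ctsd (1.90-fold), Ctsb and Ctsl (1.76-fold, with a second probe set at 0.17) and the muscle ubiquitin ligase Trim63 (1.81-fold) were the most different, while Fbxo32, another muscle ubiquitin ligase, had a log2 ratio of -0.42. Oxidative stress genes and metallothioneins had a median of 0.24, above 9930 of 10000 random lists, led by Nqo1 (1.81-fold). That list stood apart under 6 of 9 alternatives, and not with the median over probe sets, where it was 0.074. Oxidative phosphorylation (median -0.047 over 40 genes) and fatty acid oxidation (-0.058 over 22 genes) did not stand apart. Nor did heat shock genes (0.17 over 18), the cell cycle (0.13 over 27), ER stress and growth arrest (0.052 over 15), Schwann cell and nerve markers (-0.073 over 4), the circadian clock (-0.18 over 13) or reference genes (-0.076 over 12). The circadian clock stood apart under 4 of 9 alternatives, with medians from -0.26 to -0.22, and oxidative phosphorylation under quantile normalization, with -0.095. Single genes in these lists were more different, among them the small heat shock protein Hspb7 (3.37-fold higher, with a second probe set at 0.64), Gadd45a (2.83-fold) and the proliferation marker Mki67 (2.21-fold higher), while myelin basic protein, Mbp, was 2.18-fold lower, with other probe sets at -0.37 and -0.74. In all, 17 of 29 lists stood apart, 6 above and 11 below. Some of them share genes, such as Cfd in the complement and adipocyte lists and Cxcl10 in the cytokine and interferon lists. They are therefore not 17 separate results.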

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

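The gene counts used probe sets with 1 gene symbol. Among the 3260 other measured probe sets, 31 were at least 2-fold higher in the stimulated limb and 54 at least 2-fold lower. Among those with no gene listed that were measured on both arrays, 1374529_at had a log2 ratio of 2.12 (224 against 51.4, 4.36-fold higher) and 1382601_at of 1.35 (204 against 80.1, 2.55-fold higher). The 31 probe sets and these 2 were picked out because they carry a signal above that of the control sample in data that no comparison used. On the other side, 1393469_at had a log2 ratio of -1.59 and 1397604_at of -1.46. With 1 sample per group, neither an outlying sample nor a difference between effects could be looked for.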

How the results depend on the processing

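No paired analysis was possible because each group has 1 array and no test was made. Leaving out a replicate was likewise not possible. Directions of the 17 lists that stood apart were kept under all 9 alternatives of scaling, floor and probe set choice, taken relative to the median gene for spike-in scaling, and 15 of them stood apart in every one. The exceptions were the fast-fibre and the oxidative stress lists. Of the others, the circadian clock stood apart under 4 alternatives and oxidative phosphorylation under 1. The spike-in scaling was chosen after the data were seen. It moved the median gene to 0.39 and the counts to 525 higher and 44 lower, and 11 of 29 list medians changed sign when not taken relative to that gene. Relative to it, 127 genes were higher and 167 lower, and the medians were -0.74 for cytokines, -0.48 for angiogenesis, -0.29 for lymphocyte and -0.33 for Schwann cell markers. Counts depended on the floor and the threshold. With the floor at the 25th percentile, 474 genes were higher and 596 lower, and the SD between probe sets was 0.60. With the floor at the 75th percentile there were 52 and 49 genes, and that SD was 0.33. A pseudocount in place of the floor gave 82 and 89, a 1.5-fold threshold 656 and 691, and a 3-fold threshold 38 and 22. Counting probe sets gave 206 higher and 296 lower. The causes of the following shifts were not tested. For the fast-fibre list, the median was -0.027 with quantile normalization and -0.35 with loess. With the lower floor, medians were -0.67 for cytokines, -0.53 for angiogenesis, 0.15 for mast cell and 0.23 for Schwann cell markers. With the higher floor, they were -0.25 for cytokines, 0.51 for red cells and platelets, -0.67 for interferon genes, -0.23 for matrix proteases, 0.25 for slow-fibre genes, -0.38 for Schwann cell markers and 0.035 for the cell cycle, and no lymphocyte marker was left. With the pseudocount, they were -0.24 for cytokines, -0.69 for interferon genes, -0.44 for complement, -0.15 for matrix proteases and 0.43 for regeneration. With the median over probe sets, they were -0.97 for interferon genes, 0.38 for slow-fibre genes, 0.074 for oxidative stress and -0.92 for adipocytes. Without suffixed probe sets, they were 0.67 for slow-fibre genes, -1.54 for adipocytes and -0.37 for Schwann cell markers. That setting also turned Ciita to 0.054, and it left 9 named genes, among them Spp1, Obp3 and Kdr, without a probe set. The main probe sets of Ciita, Spp1, Obp3 and Kdr end in _a_at, which does not mark cross-hybridisation with other genes. Apart from Ciita, no named gene that was at least 2-fold different changed direction. Signals near the floor limit what can be said of dim genes such as Chrnd, Rsad2 and Mx2.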

Other observations

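Proteasome subunits, a list written before its values were looked at, had a median log2 ratio of 0.28, above 9999 of 10000 matched random lists, and 28 of 30 measured subunits lay above 0. Differences of single subunits were small, for example 0.56 for Psmc3 and 0.55 for Psmd5, and 0 of them reached 2-fold. One of them, Psma1, was also in the protein breakdown list, and without it the median was 0.30. Ribosomal protein genes of mean signal 2000 or more, picked after their values were seen, had a median of 0.23, with 1 of 36 below 0. The apolipoprotein gene Apoe was 4.34-fold higher and the fatty acid binding protein gene Fabp5 3.58-fold higher.

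The tests that follow were chosen after the results they bear on were seen. The lysosome list was written before its values were looked at, apart from Gusb, which the reference genes also hold, but its comparison with the macrophage markers was chosen after. Macrophage markers were higher, with Spp1 and Gpnmb far above the rest. A lower share of muscle fibres as the only change would raise all other cell types alike. Against that, the endothelial median lay below the macrophage median by a log2 difference of -1.26. Both medians were known when this comparison was chosen. It cannot weigh a lower fibre share that came together with other changes, so that stays open. Fast-fibre and glycolysis medians were lower, at -0.42 and -0.36, and the slow-fibre median was higher, at 0.89. Gpnmb lay 5.93 SDs and Spp1 11.3 SDs above the mean of the 22 other markers, 0.66. A larger number of macrophages that raised all their transcripts by 1 common fold would not give such distances. Both genes were picked for standing apart, however, and the other markers themselves varied with an SD of 0.58. A larger number of macrophages therefore stays open. A phagocytic load of the macrophages cannot be told from their number, as 31 lysosome genes had a median of 0.32, above all 10000 random lists, and 0.32 over 30 without Gusb, but below the 0.66 of the macrophage markers, and more macrophages would raise lysosome genes too. Muscle fibres and other cells also express them, so their source was not tested, and Spp1 and Gpnmb rest on 1 probe set each.

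Slow-fibre genes and the tendon genes Tnmd, Thbs4 and Fmod were higher together. A scaling difference that depends on signal would move the signal-matched random lists as well, and their median was 0.033. The slow-fibre median after loess was 0.88, above all 10000 random lists. Loess uses the same mean signal as the matching, so this adds little. Tissue nearer to tendon may account for the tendon genes, as 6 others measured had a median of 0.33, above 9869 of 10000 random lists, with 0.29, above 8746, over the 3 left with the floor at the 75th percentile and 0.81, above 9995, over 7 with it at the 25th, but Clec3b among the 6 was at -0.84, and Col1a1 and Col1a2, at -0.26 and -0.38, were lower where the test needed them not to be, so it was not met and this stays open. More slow fibres could account for the slow-fibre genes and stay open, as 11 other genes of slow fibres had a median of 0.13, above 8071 of 10000 random lists, with Myoz2, a Z-disc gene, at 1.48, Ldhb at 1.08 and Car3 at -0.91. That median was above all random lists with quantile normalization, at 0.47, and without the 3 genes that other lists hold, at 0.62 over 8, but this list was written after some values were seen.

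Interferon-stimulated genes were lower in the pricked limb. Against noise of low signals, the 14 members left with the floor at the 75th percentile had a median of -0.67, below all 10000 random lists. Fewer endothelial cells could lower such genes as well, and cannot be told apart, as the interferon median differed from the endothelial one by -0.19, against a combined SD of 0.16 of the random lists, and passed 2 SDs under 1 of 9 alternatives, the median over probe sets, at -0.38. This comparison replaced a first one whose limit had been set knowing its count, of 5 of 19 interferon genes below the lowest endothelial marker by over 1 probe set SD. Whether the control limb was high or the pricked limb low was not tested, since muscle of an untreated animal was not analysed here.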
